A study of Mus musculus with 11 samples.

How the data were processed

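Gene expression was measured in whole pancreas of 30-day-old female Balb/C offspring on 11 Affymetrix mouse arrays. Dams received a diet with 20% or 8% protein during gestation, and the offspring were injected with streptozotocin (STZ, 35 mg per kg) or vehicle (sham) daily on days 1 to 5. Dam and litter did not enter the design used here, and the offspring were treated as independent. Since the diet was given to the dams, differences between litters cannot be told apart from diet in the diet contrasts. The arrays form 4 groups: control sham (n = 3), control STZ (n = 2, replicates 1 and 3), low protein sham (n = 3) and low protein STZ (n = 3). A replicate 2 of the control STZ group was not used here. The values are the authors' deposited log2 signals per probe set. RMA and Partek 6.5 are named, per the submitters' processing notes, without a role or an order. The genome build and the authors' statistical test are not given in the sources used here, and detection calls were not used here. Array medians lay between 7.92 and 7.97, so no further scaling was applied in the fit reported.

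Probe sets were named from the GEO platform table. Of 45101 probe sets, 34958 carried 1 gene symbol, 932 carried several and 9211 carried none, and the last 2 kinds were left out. Each of the 18194 genes was represented by its probe set with the highest mean over the 11 arrays. Genes whose mean lay at or under 6.866, the 0.25 quantile of all probe set means, were not tested (2297 genes), which left 15897. Ins1, the other insulin gene of the mouse, had no probe set of its own and was not analysed here. The Ins2 probe set may also hybridise with Ins1 transcripts. The number of arrays limits the precision of each value.

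One linear model with 4 group means was fitted across all genes with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided tests). Pairwise contrasts, their means over diets or injections and the difference of the STZ effects between diets were tested, with Benjamini-Hochberg adjustment over the 15897 genes and a threshold of 0.05. The arrays called control sham enter both the STZ contrast in the control diet and the diet contrast in sham animals, so these contrasts are not independent. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 39 lists of a comparison, again with a correlation estimated from the data, and with the fry rotation test. Counts of list members are given adjusted over all genes tested and adjusted over the list alone. Differences are log2 values with the standard error (SE) of the fit, and group values are means with the SD over arrays. Tables were prepared with Python 3.11.15.

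The groups, contrasts, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. Under that rule each comparison names Ins2, Iapp, Gcg, Sst and Ppy (and Ins1 where measured), up to 8 of the largest rises and falls past the threshold, and up to 4 members with the smallest p of each list described. Where fewer than 4 genes passed in a direction, genes with the smallest p filled up to 4 and are given as not passing. The fit was tested on simulated data with 200 changed genes on the design of each comparison.

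Alternatives were a replicate block, a fit with only the 2 groups compared, moderation with trend and robust settings, array weights, cyclic loess scaling, no filter on dim genes, every probe set tested, an unadjusted p under 0.05 with a 1.5-fold minimum, covariates for RNA integrity and for B cell transcripts, and each array left out in turn. Added after the data had been seen were a covariate for the hybridisation controls (bacterial and phage transcripts added to each sample), a fit without the arrays at both ends of the first principal component, and fry.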

Results

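Whole pancreas RNA from 30-day-old female Balb/C mice was hybridised to 11 arrays in a design with 2 factors, maternal dietary protein in gestation and neonatal injection. Streptozotocin is taken up by insulin-producing β cells and kills them, and repeated low doses leave part of the β cells alive. The design asks how the pancreas differs weeks after this loss, and whether protein restriction before birth alters that state. Correlations between arrays ranged from 0.9828 to 0.9946 within groups and from 0.9778 to 0.9944 between groups. The first principal component carried 38.4% of the variance, with control sham 1 and low protein STZ 1 at its ends, and the second carried 13.7%.

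Transcripts of β cells were highest in control sham pancreas and lower in each of the other 3 groups. Ins2, which encodes insulin, averaged 14.97 ± 0.23 (SD, n = 3) in control sham, 13.25 ± 0.22 (n = 2) in control STZ, 13.88 ± 0.60 (n = 3) in low protein sham and 13.13 ± 0.38 (n = 3) in low protein STZ arrays. G6pc2, the islet form of the glucose-6-phosphatase catalytic subunit, averaged 9.10 ± 0.72, 6.71 ± 0.13, 7.22 ± 0.37 and 7.11 ± 0.08 in the same order. With limma, 0 genes passed the threshold over all 15897 genes in any of the 7 comparisons, and the conclusions on groups of genes rest on the lists. No list passed with an estimated correlation in any comparison. In simulated data the same fit recovered 90% of 2-fold changes for STZ in the control diet and 92% for diet in sham animals. For the difference of the STZ effects it recovered 70% of 2-fold and 38% of 1.5-fold changes. These shares describe the simulated genes and may not hold for the arrays. Ins2 and G6pc2 differed by more than 2-fold between control sham and control STZ arrays, and neither passed over all genes. The absence of passing genes therefore does not exclude 2-fold changes.

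**Figure D1:**
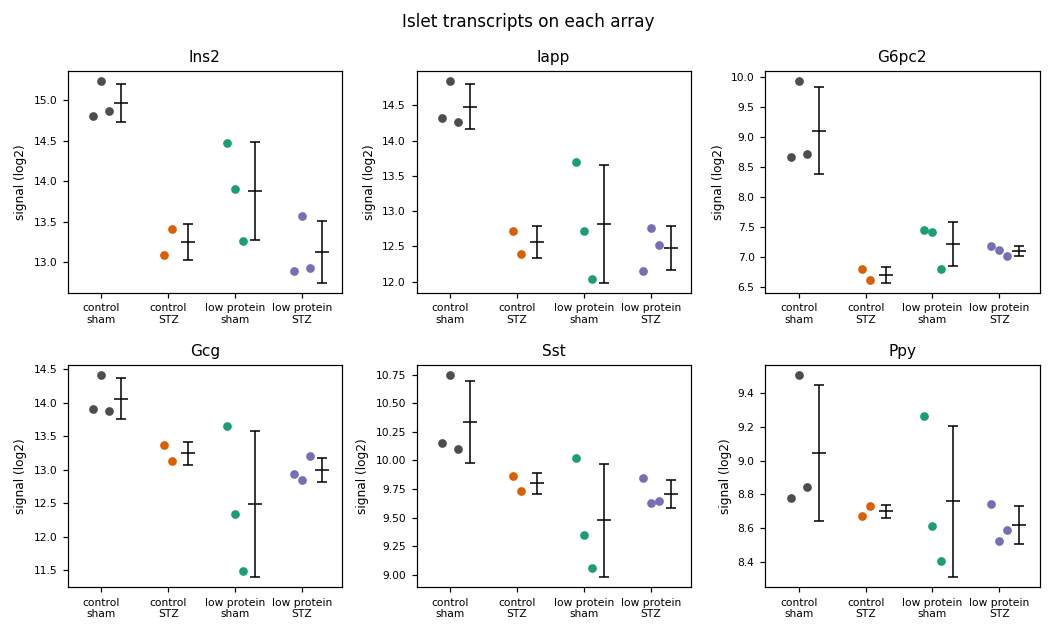
Signal (log2) of 6 islet transcripts on each array, by group; points are arrays, and the bar beside them is the mean with the SD (n = 3, and n = 2 for control STZ). Ins2, Iapp and G6pc2 are highest on the 3 control sham arrays, with Ins2 between 14.81 and 15.24 there and at or under 13.41 on both control STZ arrays.

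The contrast of STZ with sham in offspring of control dams asks what the β-cell toxin left behind at 30 days. Ins2 was 3.29-fold lower (log2 difference -1.72 ± 0.31 SE, 2 STZ and 3 sham arrays), and Iapp, encoding the amyloid peptide secreted with insulin, was 3.79-fold lower (-1.92 ± 0.38). G6pc2 differed by -2.39 ± 0.33, a size that may not be exact, since its mean after STZ (6.71) lay under the limit of 6.866 set for dim genes. Cltrn, a transmembrane protein of β cells and kidney, averaged 7.74 ± 0.12 (SD) after STZ against 8.74 ± 0.47 in sham arrays. Hormones of other islet cells differed less: Gcg (glucagon) by -0.82 ± 0.46, Sst (somatostatin) by -0.53 ± 0.26 and Ppy (pancreatic polypeptide) by -0.34 ± 0.25. None of these genes, those of β cells included, passed over all genes. Both STZ arrays lay below all 3 sham arrays for Ins2, Iapp and G6pc2.

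As a group, the β-cell identity and glucose sensing genes fell (mean log2 difference -0.44, 17 of 20 tested members lower). The camera test gave an adjusted p = 5.98e-08, and adjusted p = 0.141 with an estimated correlation. Of these 20 genes, 6 passed adjusted over the list alone and 0 over all genes tested. G6pc2 had an adjusted p of 0.000396 over the list alone and 0.315 over all genes. The number passing dropped to 3 without control sham 3, control STZ 1 or control STZ 3. Islet hormones fell too (mean -0.83, 7 tested; adjusted p = 2.09e-05, and adjusted p = 0.676 with an estimated correlation), with 2 members, Ins2 and Iapp, passing adjusted over the list alone and 0 over all genes. Without low protein sham 1, 5 hormone genes passed. Secretory granule proteins of endocrine cells, the pan-endocrine list, averaged -0.26 over 20 genes (adjusted p = 0.000597, and adjusted p = 0.676 with an estimated correlation). Its members Scg2 (-1.02 ± 0.30), Chga (-0.77 ± 0.23), Scg3 (-0.49 ± 0.15) and Chgb (-0.43 ± 0.11), granins of dense-core vesicles, each had an adjusted p of 0.0352 over the list alone and none passed over all genes. The pan-endocrine call ended without control sham 2 (-0.20, adjusted p = 0.0588) or control STZ 1 (-0.24, adjusted p = 0.0509). No granin passed without control sham 1 or 2, either control STZ array or low protein STZ 2, and 7 members passed without low protein sham 1.

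Other tissue groups moved by smaller amounts in the same contrast. Cell cycle genes fell (mean -0.20, 31 of 41 lower; camera adjusted p = 3.39e-06, and adjusted p = 0.676 with an estimated correlation), with 0 members passing adjusted over the list alone or over all genes. Examples not passing were Mcm5 (-0.78 ± 0.28) and Cdc6 (-0.31 ± 0.09), both needed to license DNA replication, and the spindle protein Nusap1 (-0.33 ± 0.09). That call ended without control sham 1 (-0.07, adjusted p = 0.0819), and without control sham 2 the mean was -0.33 with 8 members passing. Stroma and extracellular matrix genes fell (mean -0.20, 28 of 29 lower; adjusted p = 4.26e-06, and adjusted p = 0.676 with an estimated correlation), with 0 members passing adjusted over the list alone or over all genes. Among them were Vim (-0.63 ± 0.28), an intermediate filament of mesenchymal cells, and Col6a3 (-0.32 ± 0.14), a collagen VI chain. Without control sham 3 the stromal call ended (-0.07, adjusted p = 0.101), and without control sham 1 there were 2 stromal members passing.

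Acinar digestive enzymes fell slightly (mean -0.14, 24 of 24 lower; adjusted p = 2.09e-05, and adjusted p = 0.818 with an estimated correlation), with a call that ended with cyclic loess scaling (-0.03, adjusted p = 0.602) or without control STZ 1 (-0.10, adjusted p = 0.0509). Unfolded protein response genes rose (mean 0.26, 18 of 23 higher; adjusted p = 0.0125, and adjusted p = 0.818 with an estimated correlation). Examples are Sdf2l1 (1.18 ± 0.40) and the chaperone Hyou1 (0.61 ± 0.26), both of the endoplasmic reticulum. This rise was no longer called without control STZ 1 (0.06, adjusted p = 0.718), without control sham 3 (0.18, adjusted p = 0.234) or with the RNA integrity covariate (0.21, adjusted p = 0.0754), and was 0.45 without control STZ 3. Antigen presentation genes rose by a mean of 0.10 (13 of 17 higher; adjusted p = 0.0325, and adjusted p = 0.676 with an estimated correlation), including the class I heavy chain H2-K1 (0.42 ± 0.15). No member of the last 3 lists passed adjusted over the list alone or over all genes. The antigen presentation call ended without control STZ 1 (0.01, adjusted p = 0.723) or control sham 1 (0.08, adjusted p = 0.186), and under array weights and each of the 3 covariates, and was 0.18 without control STZ 3.

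Over all genes, limma called 0 for STZ in the control diet, against 644 at an unadjusted p under 0.05 (305 higher, 339 lower). The genes with the smallest p among those higher were Zfp819 (0.41 ± 0.08), Stum (0.32 ± 0.07), Gm20346 (0.42 ± 0.09) and Atp2c2, a Golgi calcium and manganese pump (0.55 ± 0.12), and Cenpq, a centromere protein, was among those lower (-0.45 ± 0.09). None of these passed (adjusted p = 0.999 each). Camera called 8 lists, 2 higher and 6 lower, and 5 without control STZ 1. Fry called 0 lists here.

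In offspring of protein-restricted dams, the contrast of STZ with sham showed smaller differences in β-cell transcripts. Ins2 was 1.68-fold lower (-0.75 ± 0.28, n = 3 and 3) and Iapp 1.27-fold lower (-0.34 ± 0.34), while Gcg was 0.50 ± 0.41 higher and Sst 0.23 ± 0.23 higher, and Ppy differed by -0.14 ± 0.22. None of these passed (adjusted p = 1 over all genes). The difference in Iapp turned to 0.10 and that in Ppy to 0.11 without low protein sham 1, the array of its group with the highest hormone signals. Limma called 0 genes, with 412 at an unadjusted p under 0.05 (108 higher, 304 lower). Those with the smallest p, none passing (adjusted p = 1), included the zinc finger protein Phf20 (0.45 ± 0.10) and the leukotriene C4 synthase Ltc4s (0.28 ± 0.06) among those higher, and Commd6 (-0.43 ± 0.11) and the adaptor subunit Ap1g2 (-0.30 ± 0.07) among those lower.

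Of the lists, 4 passed camera in the low protein diet, and fry called 0. The β-cell list was not among them, with means of 9.01 ± 0.08 (SD, n = 3) in sham and 8.95 ± 0.07 (n = 3) in STZ arrays. Mitochondrial respiratory chain genes fell (mean -0.19, 32 of 34 lower; adjusted p = 2.07e-05, and adjusted p = 0.958 with an estimated correlation), with the cytochrome oxidase subunit Cox6c at -0.34 ± 0.14 and the complex I subunit Ndufs4 at -0.26 ± 0.13. Without low protein STZ 1 the mean was -0.02 (adjusted p = 0.715), and it was -0.12 without low protein sham 1. The call also ended with array weights (-0.08, adjusted p = 0.501) and the B cell covariate (-0.09, adjusted p = 0.191), and cyclic loess gave -0.09 (adjusted p = 0.00546). Acinar digestive enzymes averaged -0.10 over 24 genes (adjusted p = 0.017, and adjusted p = 0.958 with an estimated correlation), a direction that turned without low protein STZ 1 (0.06) and with cyclic loess scaling (0.16). The call also ended without low protein sham 1 (-0.08, adjusted p = 0.0795) or low protein sham 2 (-0.10, adjusted p = 0.0559), and the mean was -0.21 without low protein STZ 3. With only these 2 groups in the fit (-0.10), array weights (-0.05), the B cell covariate (-0.05) or the hybridisation control covariate (-0.05) the acinar call ended too.

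Markers of neighbouring tissues moved little. Intestinal epithelium genes averaged 0.06 higher (13 of 14 higher; adjusted p = 0.017, and adjusted p = 0.878 with an estimated correlation), with the mucin Muc2 at 0.18 ± 0.09. B-cell genes averaged 0.05 higher (11 of 16 higher; adjusted p = 0.0295, and adjusted p = 0.958 with an estimated correlation), with the lymphocyte receptor Btla at 0.18 ± 0.07. The intestinal call ended without low protein sham 3 (0.04), low protein STZ 1 (0.05) or low protein STZ 3 (0.05), and with array weights (0.04) and the RNA integrity (0.05) and B cell (0.05) covariates. The B-cell call ended without low protein sham 1 (0.03), low protein sham 2 (0.05), low protein STZ 1 (0.03) or low protein STZ 3 (0.05), and its mean was 0.08 without low protein STZ 2. It ended as well with array weights (0.01), cyclic loess (0.06), the replicate block (0.05) and the RNA integrity covariate (0.05). No member of these 4 lists passed adjusted over the list alone or over all genes. Without low protein sham 1 the number of lists called was 9, and without low protein sham 2 it was 2.

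Whether STZ acted differently in the diets was tested as the difference of the STZ effects, low protein minus control. It was positive for G6pc2 (2.28 ± 0.44), Iapp (1.58 ± 0.52), Gcg (1.32 ± 0.62), Ins2 (0.97 ± 0.42), Sst (0.76 ± 0.34) and Ppy (0.20 ± 0.34). For G6pc2, Iapp, Ins2 and Ppy the STZ effect was less negative in the low protein diet. For Gcg and Sst its sign differed, the mean of both being -0.68 ± 0.42 in the control and 0.37 ± 0.38 in the low protein diet. The β-cell list moved with these genes (mean 0.38, 14 of 20 positive; camera adjusted p = 4.72e-05, and adjusted p = 0.42 with an estimated correlation). So did islet hormones (mean 0.78, 7 of 7 positive; adjusted p = 0.000247, and adjusted p = 0.67 with an estimated correlation). G6pc2 alone passed adjusted over the β-cell list alone (adjusted p = 0.00713), 0 hormone genes did, and 0 of either list passed over all genes. G6pc2 no longer passed without control STZ 3. Its signal was dim in 3 of the 4 groups, under the limit for dim genes (6.866) in control STZ arrays (6.71) and close to it in both low protein groups (7.22 and 7.11). Without low protein sham 1, 4 β-cell and 5 hormone genes passed over their list alone. The sign for Ppy turned without control sham 2 (-0.03). The sham level itself differed between diets, with Iapp at 14.48 in control and 12.82 in low protein sham arrays.

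Limma called 0 genes for this difference, with 566 at an unadjusted p under 0.05 (214 higher, 352 lower). Those with the smallest p included Phf20 (0.70 ± 0.16) and S100a4 (0.55 ± 0.14) with a positive difference, and Gm20346 (-0.69 ± 0.12), Zfp819 (-0.55 ± 0.10) and Atp2c2 (-0.77 ± 0.17) with a negative one, none of which passed (adjusted p = 1). Camera called 8 lists, 6 positive and 2 negative, and fry 0. The number was 5 without control sham 3, 4 without control STZ 1 and 5 without low protein STZ 1.

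Averaged over both diets, STZ left Ins2 2.35-fold lower (-1.23 ± 0.21, 5 STZ and 6 sham arrays) and Iapp 2.19-fold lower (-1.13 ± 0.26). G6pc2, near the limit for dim genes in both STZ groups, differed by -1.25 ± 0.22. Gcg (-0.16 ± 0.31), Sst (-0.15 ± 0.17) and Ppy (-0.24 ± 0.17) differed by less than their error or little more, and the sign for Gcg turned without low protein sham 1 (0.13). β-cell genes fell as a list (mean -0.25, 16 of 20 lower; adjusted p = 6.05e-06, and adjusted p = 0.326 with an estimated correlation). Of its members, 4 passed adjusted over the list alone and 0 over all genes, the vesicle docking protein Sytl4 (-0.28 ± 0.08) among them. Without control STZ 3 that number was 2. The list's fall came mostly from the control diet, where its mean was 9.38 in sham and 8.95 in STZ arrays. In the low protein diet the means were 9.01 and 8.95, and the list was not called there. Limma called 0 genes, against 514 at an unadjusted p under 0.05 (136 higher, 378 lower), and the smallest adjusted p was 0.999. Beside Ins2 and G6pc2, the smallest p belonged to the leukocyte adaptor Lat2 (0.26 ± 0.06), Gtf2h4, a subunit of a DNA repair and transcription factor (-0.35 ± 0.07), and Tmem107 (-0.44 ± 0.10), none passing. Camera called 11 lists (3 higher, 8 lower) and fry 0. The number was 7 without control sham 1 or control STZ 1, 6 without control STZ 3 and 5 without low protein STZ 3.

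The diet contrast in sham animals asks what gestational protein restriction left in the pancreas after weeks on the control diet. Islet transcripts were lower in low protein arrays: Iapp 3.17-fold (-1.66 ± 0.34, n = 3 and 3), Gcg 2.97-fold (-1.57 ± 0.41) and Ins2 2.12-fold (-1.09 ± 0.28). G6pc2 differed by -1.88 ± 0.29, Cltrn by -1.32 ± 0.25, Sst by -0.86 ± 0.23 and Ppy by -0.29 ± 0.22. For G6pc2, Iapp, Gcg, Ins2 and Sst all 3 low protein arrays lay below all 3 control arrays. Unlike after STZ in the control diet, the glucagon and somatostatin transcripts were lower by amounts near those of Ins2, although the contrasts share the control sham arrays and their difference was not tested here.

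Islet hormones fell as a list (mean -0.86, 7 of 7 lower; camera adjusted p = 6.16e-05, and adjusted p = 0.482 with an estimated correlation), with 4 members passing adjusted over the list alone (Iapp at an adjusted p of 0.00414) and 0 over all genes. β-cell genes fell (mean -0.38, 15 of 20 lower; adjusted p = 0.00176, and adjusted p = 0.482 with an estimated correlation), with 4 members passing adjusted over the list alone and 0 over all genes. Without control sham 2 the β-cell call ended narrowly (-0.32, adjusted p = 0.0509). With cyclic loess scaling Ins2 differed by -0.64 and no longer passed over the hormone list alone (adjusted p = 0.0898).

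Endothelial genes fell in low protein sham pancreas (mean -0.21, 18 of 18 lower; adjusted p = 0.000122, and adjusted p = 0.482 with an estimated correlation). In this list the progenitor and vessel marker Cd34 stood at -0.68 ± 0.20, the capillary sialomucin Emcn at -0.42 ± 0.14 and the VEGF receptor Kdr at -0.27 ± 0.08. Stromal genes fell (mean -0.29, 26 of 29 lower; adjusted p = 6.74e-06, and adjusted p = 0.825 with an estimated correlation). Its members included Vim (-0.93 ± 0.25), the basement membrane collagen Col4a1 (-0.68 ± 0.22) and the proteoglycan Bgn (-0.50 ± 0.13). The stromal mean was -0.16 without control sham 3 and -0.17 with the hybridisation controls as a covariate, and the list still passed. No member of either list passed adjusted over the list alone or over all genes with all arrays, while 10 stromal genes did without control sham 1 and 5 endothelial genes without low protein sham 1.

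Acinar digestive enzymes, the most abundant transcripts of the organ, were lower in low protein sham arrays by a mean of -0.46, but higher by 0.13 with cyclic loess scaling (adjusted p = 0.0452). In the deposited scale all 24 members were lower and passed adjusted over the list alone, 0 over all genes (camera adjusted p = 8.74e-23, and adjusted p = 0.482 with an estimated correlation). These probe sets lie near the top of the scale (list mean 15.45 in control sham arrays, highest value of any array 15.91), so the sizes of acinar differences are not exact. The trypsinogen Prss3 differed by -0.75 ± 0.16 and the amylase Amy1 by -0.51 ± 0.12. Respiratory chain genes fell (mean -0.36, 32 of 34 lower; adjusted p = 2.58e-09, and adjusted p = 0.825 with an estimated correlation), and with cyclic loess by -0.16. Among them Cox5a (-0.71 ± 0.18), Cox7a2 (-0.65 ± 0.19) and Cox5b (-0.55 ± 0.13), subunits of cytochrome oxidase, were of the 10 that passed adjusted over the list alone (0 over all genes). Leaving out control sham 1 or 3, either control STZ array, or low protein sham 2 or 3 left 0 of these 10 passing, and 18 passed without control sham 2.

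Antioxidant genes fell in the same contrast (oxidative stress response, mean -0.20, 18 of 24 lower; adjusted p = 0.0219, and adjusted p = 0.825 with an estimated correlation), with 5 passing adjusted over the list alone and 0 over all genes. They included the peroxidases Prdx4 (-0.76 ± 0.20) and Gpx4 (-0.55 ± 0.14) and the regulator Nfe2l2 (-0.67 ± 0.14), whose other probe set gave 0.21. The antioxidant call ended without control sham 1 (-0.11), control sham 3 (-0.15), low protein sham 2 (-0.17) or low protein sham 3 (-0.18) and with cyclic loess (-0.08), and the mean was -0.35 without control sham 2. Members passing over the list alone were 0 without control sham 3 or low protein sham 3 and 9 without control sham 2. The antioxidant list averaged 10.45 in control sham arrays, and all genes with a mean signal from 10 to 12 differed by a median of -0.105. It was not compared with random lists of equal brightness in any contrast, so how much of its fall goes with brightness is not known.

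Signal of the hybridisation controls, which are added to each sample in fixed amounts, was also lower in low protein arrays. The mean of 9 such probe sets was 11.48 ± 0.22 (SD, n = 6) against 11.96 ± 0.22 (n = 5) in control diet arrays, a difference of -0.48 (two-sided exact permutation p = 0.0108, adjusted p = 0.0144 over 4 array measures). The 2 cre probe sets among them, with a mean signal of 14.59, differed by -0.62 (exact permutation p = 0.00433, adjusted p = 0.0144). The SD of log2 values over an array was 1.58 in low protein and 1.64 in control arrays (exact permutation p = 0.00866, adjusted p = 0.0144), where 0.00217 is the smallest p that the 462 splits can give. Genes grouped by brightness differed in sham animals by a median log2 difference of 0.006 for genes with a mean signal from 6 to 8, -0.11 from 10 to 12, -0.37 from 12 to 14 and -0.44 from 14 to 16. The 3' minus 5' signal of Gapdh and Actb, a measure of RNA integrity, differed by -0.10 between diets (exact permutation p = 0.593).

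**Figure D2:**
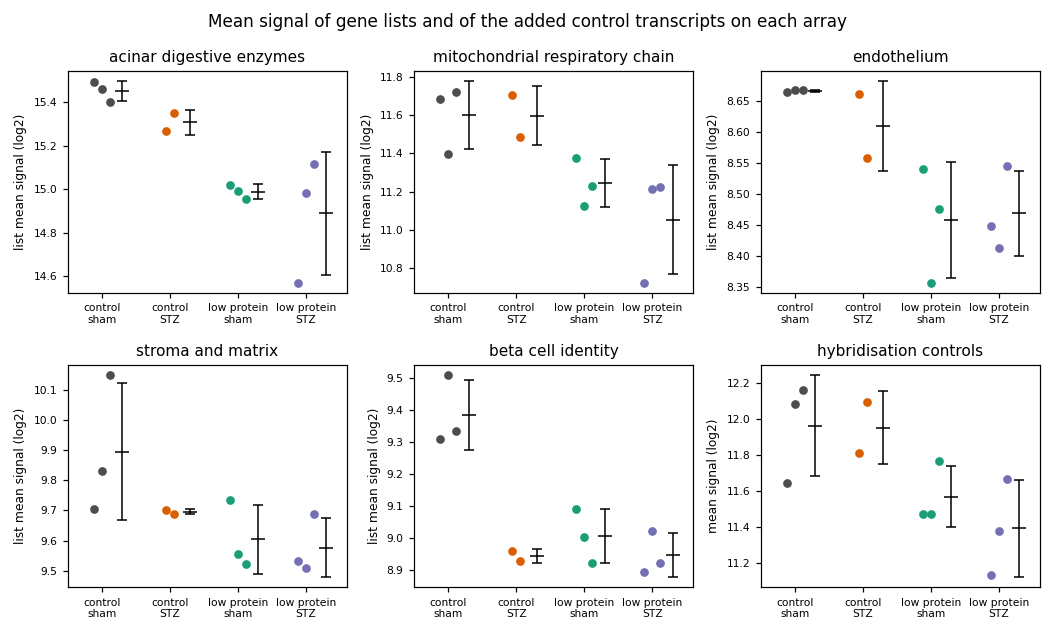
Mean signal (log2) of 5 gene lists and of the hybridisation controls on each array, by group; points are arrays, and the bar beside them is the mean with the SD (n = 3, and n = 2 for control STZ). Acinar and respiratory chain means are lower in low protein arrays, as are the added controls (11.48 against 11.96); with cyclic loess scaling the acinar difference turns to 0.13 in sham and 0.32 in STZ animals.

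**Figure D3:**
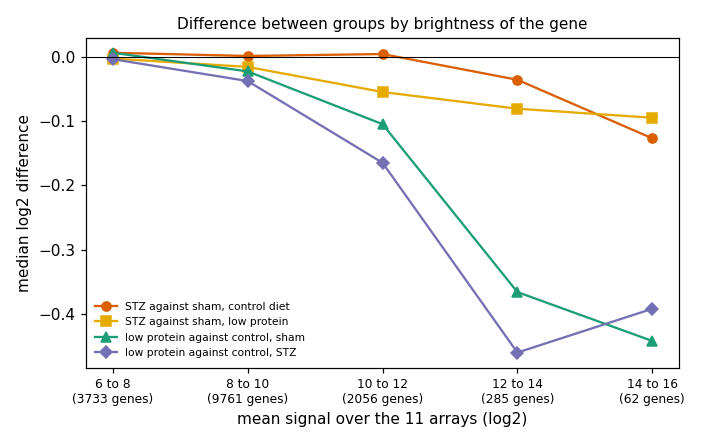
Median log2 difference (vertical axis) of genes grouped by mean signal over the 11 arrays (horizontal axis, log2), 1 line per comparison. For genes from 12 to 14 the low protein contrasts lie at -0.37 (sham) and -0.46 (STZ) and the STZ contrasts at -0.04 (control diet) and -0.08 (low protein).

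Over all genes, limma called 0 for diet in sham animals, against 1655 at an unadjusted p under 0.05 (508 higher, 1147 lower), and 126 without low protein STZ 1, which enters through the shared spread. The number was 1 without control sham 1, 3 without control sham 2 and 8 without control sham 3. The genes with the smallest p, none of which passed (adjusted p = 0.206 each), were the vesicle fusion protein Vamp3 (-0.68 ± 0.09), the endothelial junction protein Jcad (-0.65 ± 0.10) and Ngdn (-0.48 ± 0.07) among those lower. Among those higher were Vat1 (1.32 ± 0.23), Armc8 (1.18 ± 0.20), Stap2 (0.72 ± 0.13) and the small GTPase Rab6b (0.64 ± 0.11). The other 4 probe sets of Armc8 differed by between -0.07 and -0.01. Camera called 7 lists, all lower, 12 without low protein sham 1, and fry called 0.

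After STZ, the diet contrast showed little in islet transcripts and more in abundant metabolic ones. Ins2 differed by -0.12 ± 0.31 (3 low protein and 2 control arrays), Iapp by -0.08 ± 0.38, Gcg by -0.25 ± 0.46, Sst by -0.09 ± 0.26 and Ppy by -0.08 ± 0.25, none passing. With cyclic loess the signs turned for Ins2 (0.46), Iapp (0.41) and Gcg (0.25), and without single control STZ or low protein STZ arrays for Ins2 (0.04 without control STZ 3) and Iapp (0.08 without control STZ 1 or low protein STZ 1). Respiratory chain genes fell (mean -0.54, 34 of 34 lower; camera adjusted p = 4.2e-17, and adjusted p = 0.764 with an estimated correlation), and with cyclic loess by -0.26. Of these, 22 passed adjusted over the list alone and 0 over all genes, and 0 passed without control STZ 1. Cox7a2 stood at -0.88 ± 0.21, the ATP synthase subunit Atp5j at -0.83 ± 0.20 and Cox6c at -0.77 ± 0.16.

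Acinar enzymes were lower by a mean of -0.42 in low protein STZ arrays but higher by 0.32 with cyclic loess scaling. In the deposited scale 23 of 24 passed adjusted over the list alone and 0 over all genes (camera adjusted p = 4.2e-17, and adjusted p = 0.764 with an estimated correlation). Without control STZ 3 0 acinar genes passed, and the mean was -0.26 without low protein STZ 1 and -0.25 with the hybridisation controls as a covariate. Antigen presentation genes fell (mean -0.24, 15 of 17 lower; adjusted p = 0.000335, and adjusted p = 0.537 with an estimated correlation). The immunoproteasome subunit Psmb10 (-0.72 ± 0.16) alone passed adjusted over the list alone (adjusted p = 0.0165; 0 over all genes). Both that call and the list's (-0.15, adjusted p = 0.0796) ended without control STZ 1, and 5 members passed without control sham 3. Antioxidant genes fell (mean -0.35, 18 of 24 lower; adjusted p = 0.00871, and adjusted p = 0.764 with an estimated correlation), with 6 passing adjusted over the list alone and 0 over all genes. Among them were Gpx1 (-0.74 ± 0.19), Gpx4 (-0.57 ± 0.16) and superoxide dismutase Sod1 (-0.57 ± 0.14). That call ended without control STZ 1 (-0.32, adjusted p = 0.0835) or low protein STZ 1 (-0.30, adjusted p = 0.0736) and with cyclic loess (-0.18, adjusted p = 0.0666), and 0 antioxidant genes passed without either array. All genes with a mean signal from 10 to 12 differed by a median of -0.165 in this contrast.

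Stress response lists were also lower after STZ in the low protein diet than in the control diet. Unfolded protein response genes averaged -0.42 (21 of 23 lower; adjusted p = 0.00124, and adjusted p = 0.764 with an estimated correlation). The translocon subunit Sec61b stood at -0.71 ± 0.21, and 0 members passed adjusted over the list alone or over all genes (3 over the list alone without low protein STZ 3). For diet over both injections the median of this list (-0.32) stood at percentile 17.0 of random lists of equal brightness (matched median -0.25), within the range that brightness alone gives, and after STZ alone this was not tested. Amino acid response genes averaged -0.35 (23 of 26 lower; adjusted p = 0.00946, and adjusted p = 0.764 with an estimated correlation). Of its members 2, the stress protein Nupr1 (-0.86 ± 0.22) and the transcription factor Atf4 (-0.53 ± 0.13), passed adjusted over the list alone and 0 over all genes. Neither passed without either control STZ array, low protein sham 2 or 3, or low protein STZ 1 or 2. Both calls ended without low protein STZ 1 (-0.17 and -0.15) or control STZ 1 (-0.22 and -0.30), with cyclic loess (-0.10 and -0.15) and with the hybridisation control covariate (-0.25 and -0.13). The amino acid list, with a mean of 10.92 in control STZ arrays, was not compared with random lists of equal brightness. All genes with a mean signal from 10 to 12 differed by a median of -0.165 here. Cell cycle genes were called higher by a mean of 0.03 (23 of 41 higher; adjusted p = 0.0392, and adjusted p = 0.797 with an estimated correlation), with Cdc6 at 0.36 ± 0.09, and 0 members passing adjusted over the list alone or over all genes. This direction turned with the hybridisation controls as a covariate (-0.19), and the call ended without control STZ 3 (0.00), control sham 3 (0.03), low protein STZ 1 (0.02) or low protein STZ 2 (0.04), the mean being 0.06 without control STZ 1. It ended as well with cyclic loess (0.07, adjusted p = 0.171) and no filter on dim genes (0.03, adjusted p = 0.0597), and the mean was 0.08 with the replicate block and 0.07 with the B cell covariate.

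For diet after STZ, limma called 0 genes, against 1509 at an unadjusted p under 0.05 (271 higher, 1238 lower), and 1 without low protein STZ 3. Smallest in p, none passing (adjusted p = 0.348 each), were Oga, the enzyme that removes O-GlcNAc from proteins (0.72 ± 0.13), Fam71d (0.58 ± 0.11) and the G protein subunit Gnao1 (0.49 ± 0.10) among those higher. Among those lower were the phosphoinositide phosphatase Mtm1 (-0.93 ± 0.17), Atp2c2 (-0.74 ± 0.12) and the mitochondrial protein Higd2a (-0.65 ± 0.12). Camera called 7 lists (1 higher, 6 lower), 3 without control STZ 1 or low protein STZ 1, and fry called 0.

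Averaged over both injections, respiratory chain genes fell in low protein pancreas (mean -0.45, 34 of 34 lower, and -0.21 with cyclic loess; 6 low protein and 5 control arrays), with Cox7a2 at -0.77 ± 0.14 and Atp5j at -0.71 ± 0.13. Of these, 27 passed adjusted over the list alone and 0 over all genes (camera adjusted p = 5.92e-17, and adjusted p = 0.626 with an estimated correlation), 16 without control STZ 1. Acinar enzymes were lower by a mean of -0.44 but higher by 0.23 with cyclic loess. In the deposited scale 24 of 24 acinar genes passed adjusted over the list alone and 0 over all genes (adjusted p = 1.94e-23, and adjusted p = 0.62 with an estimated correlation). Endothelial genes fell (mean -0.18, 18 of 18 lower; adjusted p = 0.000722, and adjusted p = 0.62 with an estimated correlation), with the fenestral diaphragm protein Plvap at -0.46 ± 0.13. No endothelial gene passed adjusted over the list alone or over all genes, and 3 passed over the list alone without low protein sham 1 or low protein STZ 3. Antioxidant genes fell (mean -0.28, 21 of 24 lower, and -0.13 with cyclic loess; adjusted p = 0.00259, and adjusted p = 0.815 with an estimated correlation). Of them, 8 lower and 1 higher passed adjusted over the list alone and 0 over all genes, with Prdx4 at -0.71 ± 0.15. The number passing was 6 without control STZ 3 or low protein sham 3 and 14 without control sham 2. All genes with a mean signal from 10 to 12 differed by a median of -0.134 over both injections.

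Islet hormones averaged -0.48 over both injections (7 of 7 lower; adjusted p = 0.0134, and adjusted p = 0.815 with an estimated correlation), with Gcg at -0.91 ± 0.31, Iapp at -0.87 ± 0.26, Ins2 at -0.60 ± 0.21, Sst at -0.48 ± 0.17 and Ppy at -0.18 ± 0.17. The first 4 passed adjusted over the list alone and 0 over all genes. The list's call ended without control sham 2 (-0.39, adjusted p = 0.153), control STZ 1 (-0.45, adjusted p = 0.0554) or low protein STZ 3 (-0.47, adjusted p = 0.0811) and with cyclic loess (-0.25, adjusted p = 0.107). No hormone gene passed without any 1 of these 3 arrays, nor without control STZ 3, low protein sham 2 or 3, or low protein STZ 1. Antigen presentation genes averaged -0.17 (16 of 17 lower; adjusted p = 0.00259, and adjusted p = 0.62 with an estimated correlation), with 3 passing adjusted over the list alone and 0 over all genes, Psmb10 (-0.50 ± 0.11) among them, and the list's call ended without control STZ 1 (-0.13, adjusted p = 0.0702).

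Limma called 0 genes for diet over both injections, against 2438 at an unadjusted p under 0.05 (580 higher, 1858 lower), the smallest adjusted p being 0.0574. The number called was 460 without low protein STZ 3, 161 without low protein STZ 1, 102 without control sham 2, 89 without low protein STZ 2 and 5 without control sham 3, and it was 796 with array weights. The genes with the smallest p (adjusted p = 0.0574 each, not passing) included Mff, a receptor for mitochondrial fission (-0.60 ± 0.08), the RNA polymerase subunit Polr1c (-0.40 ± 0.06) and Ngdn (-0.39 ± 0.06) among those lower, and Armc8 (0.99 ± 0.15), glutathione synthetase Gss (0.76 ± 0.12) and Stap2 (0.61 ± 0.10) among those higher. The other probe set of Gss differed by -0.07. Camera called 9 lists, all lower, and fry called 3 of them, acinar enzymes, endothelium and antigen presentation (adjusted p = 0.0397 each).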

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

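The tests of islet tissue and of signal brightness given here were chosen only after the result was seen. In 8 gene lists the effect of STZ differed between the diets in the test of the difference itself. β-cell genes differed by a mean of 0.38 and islet hormones by 0.775 (range with each array left out 0.32 to 0.42 and 0.53 to 1.08). Stromal genes differed by 0.172, by 0.05 without control sham 3, which ended the call, and by 0.27 without control sham 1. Cell cycle genes differed by 0.155, by 0.02 without control sham 1, which ended the call, and by 0.28 without control sham 2. Pan-endocrine genes differed by 0.225, a call ended without control sham 2 (0.17), control STZ 1 (0.20), low protein sham 3 (0.16) or low protein STZ 1 (0.19). Respiratory chain genes differed by -0.183, and by -0.08 without control sham 2, -0.07 without control STZ 1, -0.12 without low protein sham 1 and -0.02 without low protein STZ 1, each ending the call, and by -0.29 without control STZ 3. Antigen presentation genes differed by -0.145, by -0.06 without control STZ 1 and by -0.23 without control STZ 3, the call ending without any 1 of 6 arrays. Intestinal epithelium genes differed by 0.0844, a call ended without any 1 of 6 arrays. None of the 8 passed with an estimated correlation, where the smallest adjusted p was 0.42. The fall of Ins2 and Iapp relative to Gcg and Sst after STZ was -1.14 ± 0.22 in the control diet and -0.91 ± 0.20 in the low protein diet, a difference of 0.23 ± 0.29 (95% interval -0.47 to 0.92). In the difference of the STZ effects Gcg and Sst moved by 1.04 ± 0.57 and Ins2 and Iapp by 1.27 ± 0.55, so a diet-dependent effect specific to β cells is not shown.

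Lower β-cell transcripts after STZ and in low protein sham pancreas form the first pattern weighed, where a smaller share of islet tissue in the sample would lower all islet hormones alike. After STZ, over both diets, the mean of Ins2 and Iapp fell further than the mean of Gcg and Sst, by a log2 difference of -1.028 ± 0.147 (95% interval -1.38 to -0.68, two-sided exact permutation p = 0.005, the smallest that 200 labellings allow), which argues against less islet tissue as the whole cause and leaves a loss specific to β cells, the known action of the toxin, open. Between diets in sham animals the same measure differed by -0.161 ± 0.196 (95% interval -0.63 to 0.30), with Gcg and Sst lower by -1.21 ± 0.38, as a smaller share of islet tissue would give, although Ppy, outside this measure, differed by only -0.29 ± 0.22. On low protein sham 1 the mean of the alpha, delta and PP cell list (10.07) lay above control sham 1 (9.95) and 3 (10.01). Its β-cell list mean (9.09) lay below all control sham arrays (lowest 9.31). On low protein sham 2 and 3 the alpha, delta and PP mean was lower (9.54 and 9.45). Fewer or smaller islets, or a difference in sampling of the organ, may lie behind the diet difference in sham animals, and this stays open. For STZ in the control diet and diet in sham animals, 0% and 0.02% of 10000 random lists of equal brightness had a median as low as the β-cell list's. On these arrays the β-cell list thus fell further than genes of its brightness. The random lists were drawn gene by gene and lack the correlation between list members, so these shares are no p-values. A fall with brightness alone was not tested for STZ in the low protein diet or over both diets.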

How the results depend on the processing

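Groups of genes kept their direction in most alternatives, in part by construction, and calls depended on the correlation assumed between genes. Of the results on called lists, 860 kept the call, 290 lost it and 10 turned direction. Fits with 1 array left out gave 492 of the results that kept it. For lists and genes alike, an array outside the 2 groups of a contrast cannot change its log2 difference. The estimated correlation and fry reuse the differences of the main fit. The counts are therefore no measure of robustness. Of the results on named genes, whether they passed or not, 6750 kept direction and side of the threshold, 564 no longer passed, 244 newly passed and 48 turned. In the order STZ in the control diet, STZ in the low protein diet, diet in sham, diet after STZ, difference of the STZ effects, STZ over both diets and diet over both injections, with each array left out in turn the number of genes called ranged from 0 to 1, 0 to 0, 0 to 126, 0 to 1, 0 to 0, 0 to 0 and 0 to 460, and lists from 5 to 9, 2 to 9, 6 to 12, 3 to 9, 4 to 10, 5 to 12 and 6 to 10. In that order an unadjusted p with a 1.5-fold minimum gave 43, 9, 198, 226, 60, 8 and 151 genes. Array weights gave 7 genes for diet in sham animals and 796 over both injections, the B cell covariate 1 over both injections, and leaving out control sham 1 with low protein STZ 1 gave 56 and 86. With an estimated correlation 0 lists were called in all 7 comparisons, and with fry 0 in 6 and 3 for diet over both injections. Lists numbered 11 for diet after STZ with only those groups in the fit; 0 and 7 for STZ in the low protein diet and over both diets with array weights; 3 for diet after STZ and 7 for STZ over both diets with cyclic loess; 2 for STZ in the low protein diet and 4 for the difference of STZ effects with RNA integrity; 1 for STZ in the low protein diet and 7 over both diets with B cell transcripts; 11 for diet in sham animals with hybridisation controls; and 4 for diet after STZ, 5 for the difference and 7 for STZ over both diets without control sham 1 and low protein STZ 1. With a replicate block 0 genes were called in each comparison and 10, 3, 7, 8, 7, 11 and 9 lists. Correlations of arrays with equal replicate numbers ranged from -0.23 to 0.18 over the comparisons. For diet in sham animals they were 0.09, 0.18 and 0.12, against -0.14 to 0.02 for unequal numbers, so a pairing is not excluded there. For STZ in the low protein diet equal numbers gave both signs (-0.12, 0.03 and 0.18). Contrasts with the 2 control STZ arrays give mirrored values and cannot show a pairing. The cause was not tested. Directions turned with array weights for Iapp after STZ in the low protein diet (0.0365), for Ins2 (0.163) and Iapp (0.0916) for diet after STZ, and for the test of the respiratory chain difference of STZ effects (-0.027). With cyclic loess they turned for STZ in the low protein diet in acinar enzymes (0.162), Klk1 (0.0974), Cuzd1 (0.0668), Cela2a (0.168) and Ctrb1 (0.169). For diet in sham animals they turned in acinar enzymes (0.13), Reg1 (0.0672), Cpb1 (0.153) and Prss2 (0.24). For diet after STZ they turned in acinar enzymes (0.323), Ins2 (0.462), Iapp (0.409), Gcg (0.254), Klk1 (0.238), Spink1 (0.053), Ctrc (0.357), Foxm1 (0.0661) and H2-D1 (0.0633). For STZ over both diets they turned in acinar enzymes (0.0656), Rnase1 (0.0545), Cela2a (0.0707), Gp2 (0.0224) and Zg16 (0.0571), and for diet over both injections in acinar enzymes (0.227), Reg1 (0.192), Klk1 (0.19) and Ctrc (0.268). With each array left out in turn, the Ppy difference of STZ effects ranged from -0.0268 (without control sham 2) to 0.457, Iapp for diet after STZ from -0.245 to 0.0785 (without low protein STZ 1; 0.0774 without control STZ 1), and Ins2 there from -0.34 to 0.0359 (without control STZ 3). For STZ in the low protein diet, Iapp ranged from -0.731 to 0.0966 and Ppy from -0.317 to 0.113, both highest without low protein sham 1. Without low protein STZ 1 the highest values arose for acinar enzymes (-0.212 to 0.0599), Cuzd1 (-0.362 to 0.0328), Cela2a (-0.195 to 0.0275) and Ctrb1 (-0.194 to 0.0279) in the same comparison. Reg4 for diet in sham animals ranged from -0.022 (without low protein sham 1) to 0.156, Gcg for STZ over both diets from -0.409 to 0.133 (without low protein sham 1) and Uty for diet over both injections from -0.00074 (without low protein sham 2) to 0.0877. Without control sham 1 and low protein STZ 1 together, the sign turned after STZ in the low protein diet for acinar enzymes (0.0599), Cuzd1 (0.0328), Cela2a (0.0275) and Ctrb1 (0.0279), for Iapp in diet after STZ (0.0785), for the respiratory chain in STZ over both diets (0.00508) and for Reg3g in diet over both injections (-0.00045). With the hybridisation controls as a covariate it turned for cell cycle in diet after STZ (-0.191) and for diet over both injections in Reg3g (-0.0602), Mecom (-0.0617), C1qb (0.0138), Slc4a1 (0.0312), Kdm5d (0.00853) and Uty (-0.0258). Kdm5d and Uty belong to a sex chromosome check list, which camera did not call in any comparison. Its mean was 9.28 ± 0.19 (SD, n = 3) in control sham and 9.08 ± 0.19 (n = 2) in control STZ arrays. In low protein sham and low protein STZ arrays it was 8.99 ± 0.19 and 8.85 ± 0.18 (n = 3 each). The sex of the animals was not tested from these values.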

Other observations

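The tests of signal brightness, hybridisation controls and RNA integrity below were chosen only after the result was seen, and the counts over other splits of the arrays were planned. Single genes of growth signalling and fat tissue, not described so far, had lower values in low protein pancreas over both injections, while neither list passed (means -0.08 and -0.10; camera adjusted p = 0.895 and 0.752; adjusted p = 0.95 and 0.866 with an estimated correlation). Adjusted over the list alone, 4 of 29 growth signalling genes passed lower and 1 higher, and 2 of 13 adipocyte genes lower, with 0 over all genes. Of all genes tested, 15.3% lay at an unadjusted p under 0.05 in this comparison. Counts within a list, here and below, are not adjusted for the 39 lists searched. Igf1, the circulating and local growth factor, differed by -0.45 ± 0.09 (adjusted p = 0.0187 over the list alone), from 10.82 ± 0.25 (SD, n = 3) in control sham and 10.81 ± 0.14 (n = 2) in control STZ to 10.50 ± 0.11 and 10.22 ± 0.14 (n = 3 each) in the low protein groups. With cyclic loess the difference was -0.32 and passed (adjusted p = 0.0169), and the call ended without control STZ 3 or low protein sham 2, the range with each array left out being -0.52 to -0.41. Its other 3 probe sets gave 0.01, -0.22 and -0.29. The adipocyte fatty acid carrier Fabp4 differed by -0.69 ± 0.15 (adjusted p = 0.0125 over the list alone; -0.57 and adjusted p = 0.074 with cyclic loess; range -0.81 to -0.57, the call ending without control STZ 3), with -0.63, -0.16 and 0.03 in its other probe sets. Lipoprotein lipase Lpl differed by -0.50 ± 0.14 (adjusted p = 0.031; -0.22 and adjusted p = 0.159 with cyclic loess; range -0.61 to -0.41, the call ending without any 1 of 7 arrays). None of the 3 genes passed over all genes, nor over the list alone with the hybridisation controls as a covariate (Igf1 -0.34, adjusted p = 0.203).

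Among acinar transcription factors and the Reg family, 4 single genes had lower values in low protein arrays, while neither list passed for diet over both injections (means -0.17 and -0.23; camera adjusted p = 0.69 and 0.351; adjusted p = 0.866 and 0.815 with an estimated correlation). Mecom (0.22 ± 0.11) and Reg3g (0.07 ± 0.08) stood on the higher side and did not pass. Ptf1a, the transcription factor that maintains acinar cells, differed by -0.68 ± 0.22 (adjusted p = 0.0422 over the list alone; -0.43 and adjusted p = 0.128 with cyclic loess), and Xbp1, which drives the secretory apparatus, by -0.52 ± 0.12 (adjusted p = 0.0141; -0.07 with cyclic loess). The call on Ptf1a ended without any 1 of 8 arrays and that on Xbp1 without control STZ 1. Reg1, a secreted protein of acinar cells, differed by -0.48 ± 0.11 (adjusted p = 0.00843 over the list alone) but by 0.19 with cyclic loess, and Reg3d by -0.44 ± 0.13 (adjusted p = 0.0283; -0.05 with cyclic loess), whose call ended without any 1 of 5 arrays. Laptm5, a lysosomal protein of blood cells, was higher by 0.38 ± 0.08 (adjusted p = 0.00843 over the list alone; 0.92 with cyclic loess), while other myeloid markers such as Ctss (-0.34 ± 0.14) did not pass, and its call ended without control STZ 3. With the hybridisation controls as a covariate none of these genes passed over the list alone (Laptm5 0.40, adjusted p = 0.0897).

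Lower acinar enzyme and respiratory chain transcripts in low protein arrays form the second pattern weighed. For acinar enzymes a fall with brightness alone cannot be told apart from diet. Their median stood at percentile 79.73 of random lists, but the matched genes were dimmer (13.95 against 15.15). The added cre transcripts, between these in brightness (14.59), also differed by -0.62, so the fall of bright signals was not limited to pancreas transcripts. The respiratory chain median lay under all 10000 lists of equal brightness (percentile 0, -0.46 against a matched median of -0.21). On these arrays the respiratory chain thus fell further than genes of its brightness. The random lists were drawn gene by gene and lack the correlation between list members, so this percentile is no p-value. The lower signal of the hybridisation controls, on arrays with near equal medians (7.92 to 7.97), cannot be told apart from diet for either list. With these controls as a covariate the difference was -0.295 ± 0.145 for acinar enzymes (95% interval -0.65 to 0.06) and -0.367 ± 0.206 for the respiratory chain (-0.87 to 0.14). The controls themselves differ between diets. The interval replaced a bound of 2 SE once these values were known. With the 3' minus 5' signal as a covariate the differences were -0.436 ± 0.104 (95% interval -0.69 to -0.18) and -0.456 ± 0.133 (-0.78 to -0.13). This signal hardly differed between diets, so as a covariate it could move the differences little, and the test does not decide on RNA degradation. The signal itself was not higher in low protein arrays (mean 1.53 against 1.63 in control diet arrays). Its array values ranged from 1.08 (control STZ 1) to 1.93 (control STZ 3). An effect of gestational diet on the exocrine pancreas or on mitochondria therefore stays open, since it could not be separated from the difference in the hybridisation controls. The acinar sign also depends on scaling (0.23 with cyclic loess). Only 62 genes had a mean signal from 14 to 16, so the acinar enzymes (15.15) themselves weigh in that scaling, which does not decide the sign.

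Other splits of the arrays were counted for comparisons with at least 3 arrays per group. Where 0 genes were called, every split has at least as many, so those counts hold no information on chance. With 10 splits of 3 against 3 no share under 0.05 can be reached. For STZ in the low protein diet, 0 genes were called against at most 0 in other splits (10 of 10 splits as many), 412 genes lay at an unadjusted p under 0.05 against at most 1374 (8 of 10), and 4 lists were called against at most 10 (9 of 10). For diet in sham animals the numbers were 0 genes called against at most 2 (10 of 10), 1655 at an unadjusted p against at most 1100 (1 of 10), and 7 lists against at most 15 (5 of 10). Over 100 of 200 splits for STZ over both diets, chance was not excluded for the 514 genes at an unadjusted p (79 splits as many, highest other 2590) or the 11 lists (11, highest other 17); 0 genes were called (100 by definition, highest other 8). For diet over both injections, 2 of 100 splits, the real one included, gave as many as the 2438 genes at an unadjusted p (highest other 3361). This share lies under 0.05, on the assumption that the offspring are independent. The count does not tell diet from litter, or from the hybridisation control signal and the SD of array values, in which the diets also differed. For the 9 lists chance was not excluded (21, highest other 15), and 0 genes were called (100 by definition, highest other 552). The split with 552 called genes follows the diet with 1 array moved, low protein STZ 3 standing with the control diet arrays. The one with 2590 genes for STZ sets control sham 2, control STZ 3, low protein sham 2 and low protein STZ 1 and 2 against the rest. Counts several times the real ones point to a structure of the samples, the nature of which was not tested.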
